A study of Homo sapiens with 13 samples.

How the data were processed

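Total RNA from frozen appendix tissue of 9 patients and 4 controls was extracted with a phenol-based reagent, copied into biotin-labelled cRNA and hybridised to an Affymetrix expression array, per the labels' protocols. The submitters' processing notes name GCOS 1.4.0.036, without saying which settings were used. The deposited values are a linear signal intensity for 22215 probe sets on each of 13 arrays, all above 0, with no missing values. Each array in the deposited table already had nearly the same 2% trimmed mean, between 1489 and 1494, as after scaling to 1 target, but the target, any filter and the detection calls are not given in the sources used here. The table held 0 control probe sets, so the planned ratios of 3' to 5' probe sets, a measure of RNA quality, and the fit with the GAPDH ratio as a covariate were not run.

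Probe sets were named from the platform's annotation, with symbols updated through Entrez identifiers. Exactly 1 symbol was found for 19064 probe sets, several for 1043 and none for 2108. Of those with 1 symbol, 19052 were matched by identifier, 11 by symbol or synonym, and 1 kept the annotation's symbol. The 19064 probe sets named 11960 genes. Before any fit 24 sex-linked genes, 23 genes whose level can reflect a germline deletion or haplotype, and 20 immunoglobulin or T cell receptor segments were left out. No genome build is named for the table, so no coordinates are given.

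Arrays were scaled to a common 2% trimmed mean. Values under the 20th percentile of all scaled values, a signal of 103.3, were set to it, and log2 was taken. Where 1 group alone reaches the floor its difference is understated, and where both do, it is no bound. A probe set was kept if it exceeded its array's median in at least 4 of 13 arrays, and each gene was represented by its probe set with the highest mean, which left 7659 genes. Of the 239 genes that changed, 52 had several probe sets, and in 2 of these a probe set went the opposite way. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with group as the only term and Benjamini-Hochberg adjusted p under 0.05. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The labels describe the samples as separate patients and controls, so p-values reflect spread between people, with no technical repeats. The labels give no batch, and none was tested.

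A set of 50 gene lists for cell types and processes of the appendix was fixed before the data were examined, as were the tests, the alternative settings and the rule for naming genes. Lists with at least 3 tested members, 46 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 46 lists, with the estimated correlation and fry as alternatives. The eosinophil, erythrocyte, Th1 and Th17 lists had fewer than 3 tested members and were not tested. The mean log2 signal of each list's members gave 1 score per array, compared by a two-sided exact permutation test over all 715 assignments of the arrays, whose smallest p is 0.0014. List members share 2 genes across lists, CD83 and ICAM1. Named genes were the 12 with the largest rise and the 12 with the largest fall among those past the test whose value in every patient lay on one side of the control mean, and from each list 2 to 4 tested members with the smallest limma p.

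The steps were tested on simulated data for patients against controls with 200 changed genes, over 7597 genes that passed the filter. Of 95 genes changed 2-fold and tested, 48.4% were recovered, and of 90 changed 4-fold, 91.1%. The fit made 135 calls, 7 of them false, and 0 calls where nothing was changed. Genes with changes near 2-fold can thus be missed at this number of arrays. A 2-fold shift of the neutrophil list was called by camera in 8 of 10 rounds, with 2 other lists called over all rounds. Simulated values were drawn independently for each probe set, whereas members of real lists varied together (estimated correlation 0.80 for the neutrophil list). These rounds therefore cannot show how often camera calls unshifted lists on the real arrays, where other splits gave a median of 16. The gene counts share this limit. The simulation also gave both groups the same spread, which real genes need not have (TREM1 SD 2.21 in patients and 0.43 in controls). The simulated recovery and false calls may therefore not hold on the real arrays, where 3 of the other splits gave genes past the test, up to 146.

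Alternatives covered quantile and 75th percentile scaling, the values as deposited, other floors or an offset, other filters, the mean of a gene's probe sets or every probe set, eBayes without trend or with robust estimation, array weights, other list tests and scores, and leaving out each array in turn. Added after seeing the data were a looser filter when a control was left out, and rank correlations for 1 patient array.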

Results

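Gene expression was measured in appendix tissue from 13 people, 9 patients in a study of acute appendicitis and 4 controls, with 1 Affymetrix oligonucleotide array per person. The only comparison the labels allow is patients against controls, which asks how transcript levels in the appendix differ in acute appendicitis. What the controls had in place of appendicitis is not given in the sources used here. The deposited table held a linear signal intensity for 22215 probe sets on each array. The median signal ran from 455.4 to 669.7 across arrays, at 593.8 ± 69.4 (SD, n = 4) in controls and 529.2 ± 36.4 (SD, n = 9) in patients. That difference had a two-sided exact permutation p of 0.0406, or 0.0811 after Benjamini-Hochberg adjustment over 2 array measures. The share of values at the low-signal floor was 18.6% ± 3.05 (SD, n = 4) in controls and 20.6% ± 2.41 (SD, n = 9) in patients (exact permutation p = 0.250). Over the tested genes the mean correlation between arrays was 0.899 within controls, 0.866 within patients and 0.831 between the groups. On 1 patient array the mean correlation was 0.889 with the 4 controls and 0.822 with the other 8 patients. The number of arrays, above all the 4 controls, limits the precision of every value below.

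In patients, TREM1, LILRB2, IL1RN and CCR1 were among the genes that rose, and UGT2A3, PCK1, ADH1C and 7 of 13 tested absorptive colonocyte markers were among those that fell. Of 7659 genes tested with limma, 239 changed at an adjusted p under 0.05, of which 49 were higher and 190 lower in patients. At least 2-fold changes were found in 180 of them, 32 higher and 148 lower. All 9 patients lay above all 4 controls for 28 of the higher genes, and below all 4 for 120 of the lower genes. Among all tested genes 249 had groups that did not overlap, where chance gives 0.2797% of genes. The count rested on single arrays. Without either of 2 controls, 0 genes passed in limma (smallest adjusted p = 0.0832 and 0.0804, with 1165 and 1045 genes at an unadjusted p under 0.05), and without another control 74 passed. Leaving out the remaining control gave 181, leaving out any 1 of 6 patients gave 100 to 158, leaving out either of 2 others gave 277 and 288, and leaving out the patient array that lay near the controls gave 513.

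TREM1, a receptor that amplifies inflammatory signals in neutrophils and monocytes, rose by 3.94 ± 0.98 (SE) on the log2 scale, a 15.3-fold difference in fitted values (limma adjusted p = 0.0440). Its control level, 6.96 ± 0.43 (SD, n = 4), lay close to the floor, with 1 control at it, so the fold is uncertain. Leukocyte immunoglobulin-like receptors rose as well, with log2 changes of 3.15 ± 0.72 (SE) for LILRB2, 2.58 ± 0.55 for LILRA1 and 2.31 ± 0.56 for LILRB1. The probe sets of LILRB2 and LILRB1 are of a class that can bind transcripts of related genes, so these receptors may not be separable from one another. IL1RN, the interleukin-1 receptor antagonist, was 7.54-fold higher (log2 change 2.92 ± 0.69 SE, adjusted p = 0.0375), and the chemokine receptor CCR1 was 4.28-fold higher (2.10 ± 0.44 SE, adjusted p = 0.0250). CHI3L2, a chitinase-like protein, rose by 1.66 ± 0.31 (SE), and KYNU, the kynureninase of tryptophan breakdown, rose by 1.55 ± 0.26 (SE, adjusted p = 0.0155). Over the 3 probe sets of each gene, log2 changes ran from 1.24 to 2.92 for IL1RN and from 0.94 to 1.55 for KYNU. The 12 larger rises also held S100A4 with a log2 change of 1.35, the adaptor SAMSN1 with 1.34, coagulation factor F5 with 1.32 and the lysosomal protease CTSB with 1.31. By the rule that chose these 12 genes, every patient lay above the control mean in each.

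Among the genes that fell, UGT2A3, a glucuronosyltransferase, had the smallest adjusted p of all tested genes. Its log2 signal was 10.29 ± 0.54 (SD, n = 4) in controls and 7.34 ± 0.56 (SD, n = 9) in patients, a 7.71-fold lower level in patients (limma adjusted p = 0.00401). Its probe set is of the class that can bind transcripts of related genes. PCK1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was 14.6-fold lower (log2 change -3.86 ± 0.69 SE, adjusted p = 0.0155). CHP2, a calcium-binding partner of sodium-proton exchangers, was 13.6-fold lower, and it was at the floor in 6 of 9 patients, so its fall is understated. The alcohol dehydrogenase ADH1C was 11.8-fold lower, the water channel AQP8 10.6-fold lower and the colonocyte membrane protein MS4A12 10.5-fold lower. GUCA2A, which encodes the peptide guanylin, fell by 3.15 ± 0.56 (SE). SELENBP1, a methanethiol oxidase, fell by 2.87 ± 0.41 (SE, adjusted p = 0.0143). The steroid-inactivating enzymes HSD11B2 and HSD17B2 had log2 changes of -2.87 ± 0.60 and -2.86 ± 0.62 (SE). NXPE4, at the floor in 5 of 9 patients and so also understated, fell by 2.92 and the chemokine CXCL14 fell by 2.76, with adjusted p of 0.0185 and 0.0471. UGT2A3, AQP8 and HSD17B2 were at the floor in 2 patients each, and PCK1, ADH1C, MS4A12, GUCA2A and HSD11B2 in 1. Their falls are understated as well. By the same rule, every patient lay below the control mean in these 12 genes. Of these 24 genes, CHI3L2, KYNU, SAMSN1, PCK1, CHP2, ADH1C, GUCA2A, UGT2A3, NXPE4 and SELENBP1 passed in every processing alternative that tested them with all 13 arrays. The other 14 lost their call, with the direction kept, when genes of low signal were not filtered out. TREM1 and AQP8 did not pass in 6 of 12 such alternatives and CXCL14 in 4 of 12, among them scaling to the 75th percentile.

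**Figure D1:**
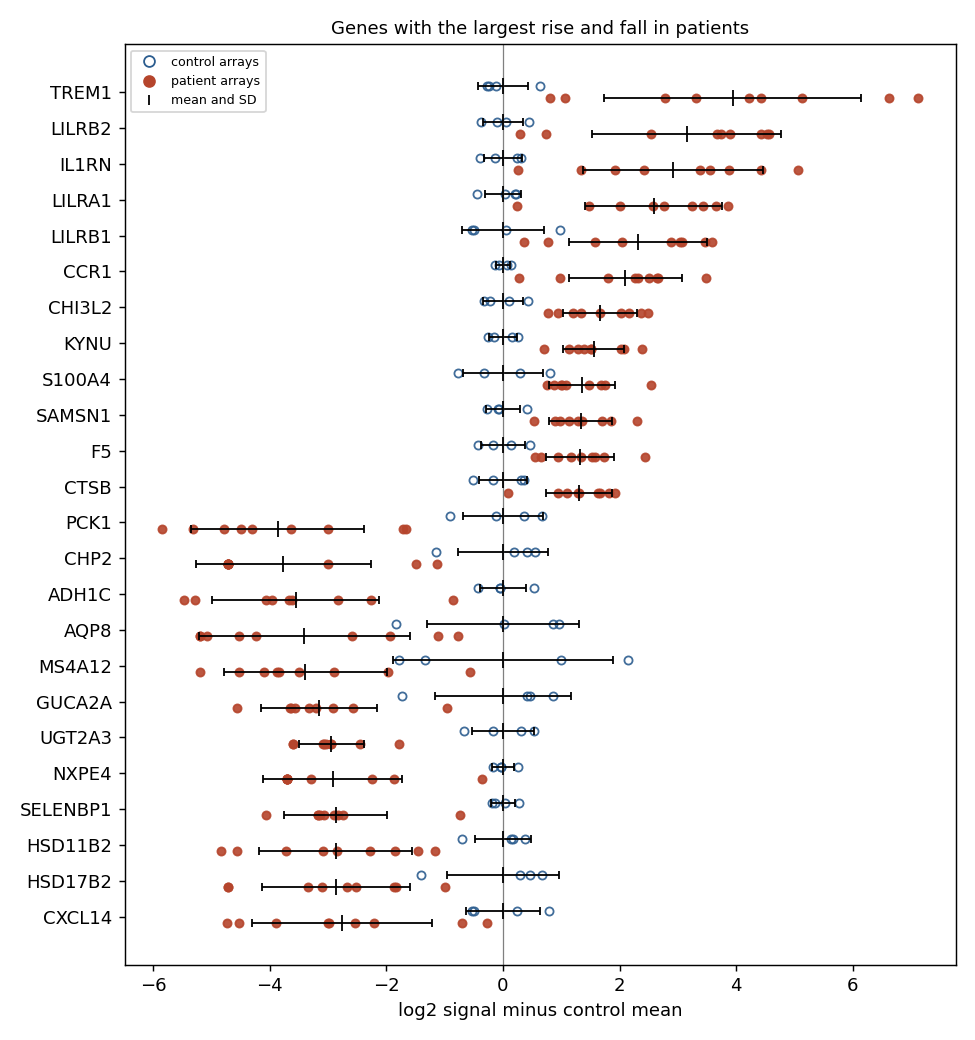
Log2 signal of the 12 genes with the larger rises and the 12 with the larger falls, on the horizontal axis as the difference from the mean of the 4 control arrays. Open circles are the 4 controls, filled circles the 9 patients, and black ticks with bars the group mean and SD. All 9 patients lie on one side of the control mean because the genes were chosen so. TREM1 spans the widest range among patients.

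Markers of neutrophils were higher as a group. The median log2 change of the 17 tested members was 2.94, a 7.68-fold difference, and 8 of 9 patients had a list score above every control. TREM1 and the aquaglyceroporin AQP9 (log2 change 4.25 ± 1.07 SE, adjusted p = 0.0459) rose over all genes tested, and 15 members did not pass. Adjusted over the list alone, 17 of 17 rose. Here and below that count applies Benjamini-Hochberg within 1 list, with no adjustment across the 46 lists. The neutrophil members varied together (estimated correlation 0.80), so these are not 17 separate results. LILRB3 (2.75 ± 0.72 SE, adjusted p = 0.0516) and HCAR3 (4.03 ± 1.08 SE, adjusted p = 0.0550) were among those that did not pass over all genes. The camera test placed the list above other genes (adjusted p = 9.0e-15; adjusted p = 0.26 with an estimated correlation). Its mean score differed by 2.91, with an exact permutation p of 0.0140 and 0.0919 after adjustment over 46 lists. The neutrophil granule list, with 4 of 13 members tested, had a median log2 change of -0.10 (camera adjusted p = 0.988), with LTF at -1.33 ± 0.98 (SE) and MMP9 at 0.26 ± 0.33 (SE), and 0 passed. The other tested members were OLFM4 and LCN2. In controls the granule list already had a score of 13.27, against 8.52 for the neutrophil list. Signal from other cells may therefore dominate it, and it does not show whether granule transcripts of neutrophils changed. Whether the neutrophil and granule lists differed was not tested.

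Other lists of innate immunity lay higher by camera. For monocytes and macrophages the median log2 change was 0.78 over 12 members, AIF1 rose by 1.04 ± 0.26 (SE), and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.0218; adjusted p = 0.49 with an estimated correlation). MARCO, a scavenger receptor at the floor in all 4 controls and in 2 of 9 patients, did not pass (log2 difference from the floor 4.01 ± 1.06 SE, adjusted p = 0.0533), and with patients at the floor too that difference is no bound. The neutrophil-attracting chemokines had a median log2 change of 1.62 over 6 members, with 0 past the test over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000167; adjusted p = 0.33 with an estimated correlation). CXCL8 was at 3.22 ± 0.85 (SE, adjusted p = 0.0533) and CXCL6 at 2.70 ± 0.76. The innate cytokines had a median of 2.32 over 6 members, again with 0 and 4 past (camera adjusted p = 0.00726; adjusted p = 0.35 with an estimated correlation), and IL1B at 2.58 ± 0.76 (SE). IL11 was at the floor in 3 of 4 controls and in 1 patient, so its fitted log2 difference of 3.17 ± 1.08 (SE) is no bound either. Of 14 pattern recognition genes LY96, the TLR4 co-receptor MD-2, rose by 1.08 ± 0.27 (SE), and 6 rose adjusted over the list alone (camera adjusted p = 8.0e-06; adjusted p = 0.26 with an estimated correlation). NOD2 was at 1.77 ± 0.51 (SE) and did not pass.

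The feedback inhibitors of inflammation had a median log2 change of 0.59 over 10 members, with IL1RN as the 1 that rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0073; adjusted p = 0.49 with an estimated correlation). The median over 13 NF-kB targets was 0.69 with 0 past either count (camera adjusted p = 0.000171; adjusted p = 0.26 with an estimated correlation), BCL2A1 at 1.65 ± 0.53 (SE) and NFKB2 at an adjusted p of 0.154. Interferon gamma targets had a median of 0.40 over 12 members and 0 past (camera adjusted p = 0.0219; adjusted p = 0.49 with an estimated correlation), whereas the 19 type I interferon targets had a median of 0.01 and were not called (camera adjusted p = 0.380), with MX2 at 0.75 ± 0.24 (SE) and IRF7 at 0.66 ± 0.23. The interferon gamma call ended with quantile normalization (camera adjusted p = 0.0679), and whether the changes of the interferon lists differed was not tested. Among 12 matrix proteases and inhibitors, the collagenase MMP1 rose by 3.61 ± 0.88 (SE, adjusted p = 0.0428) and TIMP1 by 2.05 ± 0.53 (SE, adjusted p = 0.0497), and 4 rose adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.47 with an estimated correlation). AQP9 and MMP1 changed more than most of the 12 larger rises, but not every patient lay above the control mean. The calls of AQP9, AIF1 and TIMP1 ended when arrays were scaled to the 75th percentile, that of TIMP1 also with quantile normalization. Of the 19 genes named from lists that passed and are not among the 24 larger changes, 8 passed in every processing setting with all arrays that tested them (VIL1, CLDN4, SLC26A2, L1CAM, ERBB3, DPT, HPGD and ACADS). MMP1, LMOD1, LY96, HSPH1 and CLDN3 did not in 2 settings each, nor CDX1, KLF4 and HADH in 1. With 1 array left out, MMP1 and TIMP1 lost their call in 11 of 13 fits and AQP9 and LMOD1 in 10. AIF1 lost it in 9, LY96 in 8 and HSPH1 in 6, and all 19 genes lost it in at least 2.

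Stress lists lay higher too. Of 9 heat shock genes HSPH1 rose by 1.02 ± 0.23 (SE), 3 rose adjusted over the list alone, and HSPA6 was at 2.77 ± 0.81 (SE) without passing (camera adjusted p = 2.9e-05; adjusted p = 0.26 with an estimated correlation). The 17 hypoxia and glycolysis genes had a median log2 change of 0.40 and 0 past either count, with HIF1A at 0.85 ± 0.25 (SE) and BNIP3 at 0.75 ± 0.24 (camera adjusted p = 0.000167; adjusted p = 0.49 with an estimated correlation). The 15 genes of the unfolded protein response had a median of 0.45 and 0 past either count, with TRIB3 at 0.97 ± 0.30 (SE) and MANF at 0.75 ± 0.26 (camera adjusted p = 0.000793; adjusted p = 0.26 with an estimated correlation). Endothelial markers had a median of 0.35 over 11 members and 0 past either count, with TIE1 at 0.50 ± 0.27 (SE) and KDR at 0.44 ± 0.26 (camera adjusted p = 0.0222; adjusted p = 0.49 with an estimated correlation).

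**Figure D2:**
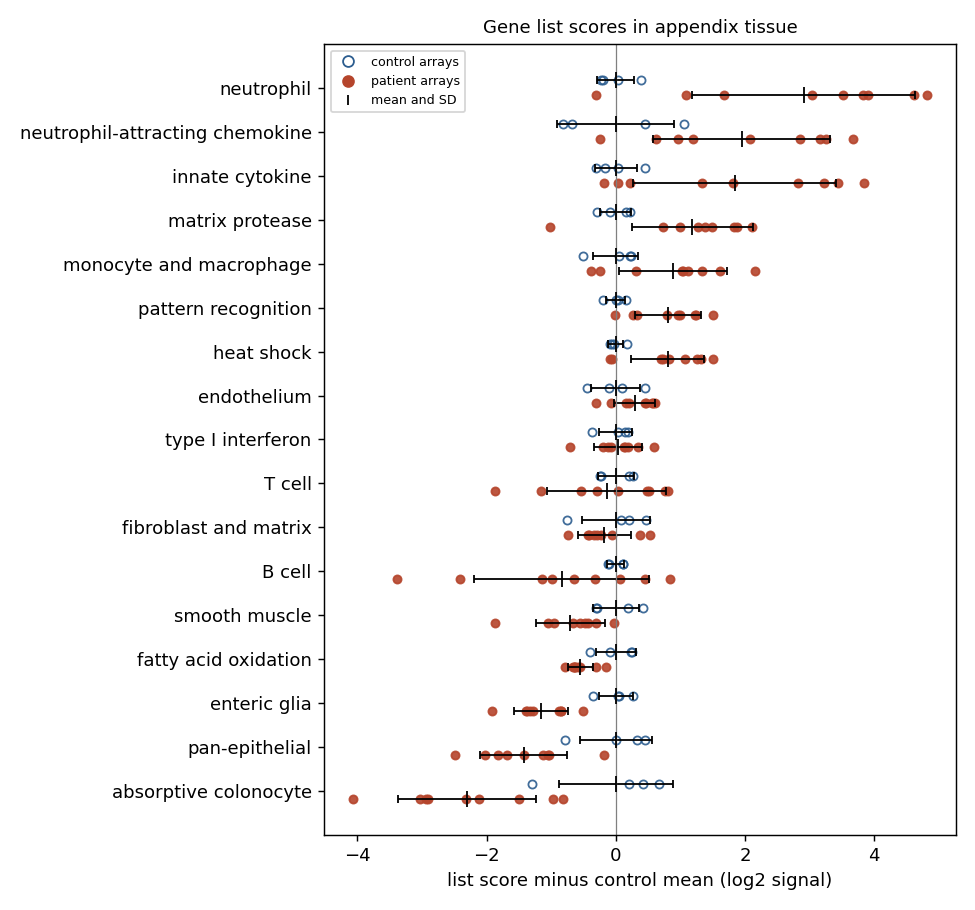
Scores of 17 gene lists, each the mean log2 signal of its tested members, on the horizontal axis as the difference from the mean of the 4 control arrays. Open circles are the 4 controls, filled circles the 9 patients, and black ticks with bars the group mean and SD. The neutrophil score lies above all controls in 8 of 9 patients, and the enteric glia score lies below all controls in 9 of 9. The enteric glia score is the mean of only 3 tested genes. Neither score passed adjustment over 46 lists (exact permutation adjusted p = 0.0919 and 0.0643).

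Epithelial lists lay lower in patients. Of 13 absorptive colonocyte genes 7 fell, 11 adjusted over the list alone, and the median log2 change was -2.01. GUCA2A, HSD11B2, MS4A12 and the sulfate transporter SLC26A2 (-1.68 ± 0.34 SE, adjusted p = 0.0233) had the smallest limma p in the list. Camera's adjusted p for the list was 1.6e-09, and 0.26 with an estimated correlation. The score differed by -2.30, below every control in 7 of 9 patients (exact permutation p = 0.00559, adjusted p = 0.0643). Of 15 pan-epithelial genes 6 fell, 11 adjusted over the list alone, with a median of -1.51 (camera adjusted p = 2.3e-09; adjusted p = 0.26 with an estimated correlation). They included the microvillus protein VIL1 at -1.89 ± 0.35 (SE), the tight junction proteins CLDN4 at -1.51 ± 0.31 and CLDN3 at -2.10 ± 0.45, and the intestinal transcription factor CDX1 at -2.43 ± 0.55. Goblet cell genes had a median of -0.70 over 10 members with 0 past either count (camera adjusted p = 0.0355; adjusted p = 0.62 with an estimated correlation), TFF3 at -1.64 ± 0.55 (SE) and CLCA1 at -1.98 ± 0.73. The 6 enteroendocrine genes were not called (median -0.45, camera adjusted p = 0.0684), with 2 lower adjusted over the list alone, SCGN at -1.42 ± 0.37 (SE) and CHGA at -1.34 ± 0.39.

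Muscle and nerve lists were also lower. Of 15 smooth muscle genes the thin-filament nucleator LMOD1 fell by 1.39 ± 0.34 (SE), 5 fell adjusted over the list alone, and MYH11 was at -0.95 ± 0.26 (SE) without passing (median -0.58, camera adjusted p = 0.000267; adjusted p = 0.49 with an estimated correlation). Of 3 tested enteric glia genes the adhesion molecule L1CAM fell by 1.39 ± 0.26 (SE, adjusted p = 0.0185) and the receptor ERBB3 by 1.87 ± 0.37 (SE, adjusted p = 0.0221), also adjusted over the list alone (camera adjusted p = 0.00726; adjusted p = 0.26 with an estimated correlation). ERBB3 is also expressed in epithelium and L1CAM in neurons, while the third member, CDH19, was at -0.20 ± 0.32 (SE). The enteric glia score lay below every control in 9 of 9 patients, with an exact permutation p of 0.0014, the smallest the design allows, and 0.0643 after adjustment. Enteric neuron genes had a median of -0.36 over 12 members, with 0 past over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.49 with an estimated correlation), UCHL1 at -0.60 ± 0.18 (SE) and STMN2 at -1.50 ± 0.46.

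Of 13 fatty acid oxidation genes the dehydrogenases ACADS and HADH fell by 1.26 ± 0.22 and 1.23 ± 0.27 (SE), and 5 fell adjusted over the list alone (median -0.45, camera adjusted p = 0.00035; adjusted p = 0.26 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.34 over 23 members with 0 past either count (camera adjusted p = 0.00172; adjusted p = 0.49 with an estimated correlation), NDUFV1 at -0.71 ± 0.22 (SE) and UQCRC1 at -0.73 ± 0.23. Among 15 immediate early genes the transcription factor KLF4 fell by 1.73 ± 0.37 (SE), 2 fell adjusted over the list alone, and EGR1 was at -1.09 ± 0.30 without passing (median -0.67, camera adjusted p = 0.0241; adjusted p = 0.67 with an estimated correlation). Another probe set of EGR1 was at -0.24, and those of HADH ran from -1.39 to -0.64. The 24 cell cycle genes had a median of -0.47 with 0 past either count (camera adjusted p = 0.00726; adjusted p = 0.71 with an estimated correlation), PLK1 at -0.86 ± 0.36 (SE) and AURKA at -0.63 ± 0.27. The 13 B cell genes had a median of -0.95 with 0 past either count (camera adjusted p = 0.0386; adjusted p = 0.71 with an estimated correlation), VPREB3 at -1.46 ± 0.73 (SE) and TCL1A at -1.47 ± 0.75. Patients varied widely in this score, at 11.12 ± 1.35 (SD, n = 9) against 11.95 ± 0.13 (SD, n = 4) in controls.

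The other lists were not called by camera, and where no count is given 0 members passed over all genes or adjusted over the list alone. Adjusted p was 0.925 for T cells (IL7R at 1.38 ± 0.41 SE, CD3E at -0.74 ± 0.45), 0.508 for NK and cytotoxic cells (CST7 at 0.59, GZMB at 0.89), 0.508 for plasma cells (SDC1 at -0.96, JCHAIN at -1.05) and 0.554 for germinal centre genes (BCL6 at 0.60, ELL3 at -0.98). It was 0.0804 for MHC class II genes (CD74 at -0.42, HLA-DPB1 at -0.60), 0.389 for dendritic cells, where CCL22 at 1.67 ± 0.44 (SE) passed adjusted over the list alone, and 0.49 for mast cells (CPA3 at -0.49, TPSAB1 at -0.67). Among fibroblast and matrix genes the proteoglycan-binding protein DPT fell by 1.69 ± 0.28 (SE, adjusted p = 0.0155), also adjusted over the list alone, while the list was not called (camera adjusted p = 0.486). In the eicosanoid list HPGD, which degrades prostaglandins, fell by 1.72 ± 0.34 (SE), with 3 higher and 2 lower adjusted over the list alone, among them ALOX5 at 0.93 ± 0.30 (camera adjusted p = 0.320). In the coagulation list F5 was the 1 that rose by either count (camera adjusted p = 0.134).

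For the remaining lists camera's adjusted p was 0.0825 for NADPH oxidase (NCF4 at 0.67, CYBB at 0.97), 0.134 for Th2 genes (IL1RL1 at 1.90, IL4R at 0.28) and 0.405 for other inflammatory chemokines (CCL4 at 1.25, CCL23 at -0.92). It was 0.390 for epithelial antimicrobial genes (PI3 at 1.51, DEFA5 at -2.17), 0.482 for complement (CFB at 0.99, C3AR1 at 1.51) and 0.508 for endothelial activation (ICAM1 at 1.04, MADCAM1 at -0.86). It was 0.370 for growth factor and wound genes (BMP2 at -0.96, GREM1 at 0.89), 0.555 for adipocytes (CIDEC at -0.47, LPL at -0.30) and 0.531 for ribosomal proteins (RPL6 at -0.08, RPS9 at 0.15). All values in parentheses are log2 changes that did not pass. The median and the mean log2 change differed in sign for coagulation (-0.03 and 0.40) and for NK and cytotoxic cells (-0.05 and 0.04), where camera's direction was that of the mean.

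In all, camera called 24 of 46 lists, 13 higher and 11 lower, and 0 with an estimated correlation. With the preset correlation, 13 of the 24 were called in every processing setting and with every array left out in turn. The B cell, cell cycle, endothelium, enteric glia, enteric neuron, feedback inhibitor, goblet cell, immediate early, interferon gamma, monocyte and macrophage, and oxidative phosphorylation lists lost their call in at least 1. All these fits reuse nearly the same arrays and a test that called a median of 16 and up to 31 lists in other splits of them. A call kept throughout is therefore no evidence by itself that a list differs between the groups. No list score passed adjustment by the exact permutation test, where 0 of 46 had an adjusted p under 0.05 and the smallest was 0.0643.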

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

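The tests of a swap and of poor quality for 1 patient array were chosen after its position had been seen, as were its rank correlations; the other tests in this part were set before their results. Within each group the highest and lowest values were tested for lying apart from the rest (Dixon's test), over 494 combinations of a group with a list score, an array measure or a named gene. Of these 26 stood apart, or 5.26%, where chance gives about 5%, and 7 of the 26 came from 1 patient array.

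On that array, which lay near the controls, the share of values at the floor was 26.18% (next patient 21.99%), and the matrix protease score was 9.665 (next 11.41). Its log2 levels were 12.11 for SELENBP1 (next 10.10), 7.193 for FAP (next 9.408), 12.32 for WARS1 (next 13.22), 8.797 for MMP1 (next 12.26) and 8.612 for MMP3 (next 12.08). Its neutrophil score was 8.22, with 9.61 the lowest of the other 8 patients and 8.91 the highest control. Of the 24 lists called by camera, its score lay within the range of the controls for 13, beyond it on the side of the patients for 6 (pan-epithelial 10.44 with a lowest control of 11.08, enteric glia 9.756 with 10.25) and beyond it on the opposite side for 5. PCK1 at 9.533 (lowest control 11.63), UGT2A3 at 8.509 (9.615) and KYNU at 10.83 (highest control 10.39) lay with the patients, in genes chosen with this array included. A swap with a control is argued against only for a swapped tissue with neutrophil signal like that of the other patients. Of the controls, 0 of 4 had a neutrophil score at or above the lowest of the other patients. A swapped tissue with less neutrophil signal stays open. The lowest control colonocyte score, 11.20, lay below the highest of the other patients, 11.68. Poor array quality stays open, since 26.18% of its values were at the floor and its median signal, 455.4, was the lowest of the 13 arrays; its mean correlation with the controls, 0.889 (0.879 by ranks), is how it was noticed and decides nothing. A control tissue with a wrong label stays open too. Over 500 genes chosen without the array and without 1 control in turn, it lay nearer the patient mean than the held-out control in 4 of 4 rounds, which was the bound set beforehand against that explanation. The positions overlapped across rounds, however, at 0.293 to 0.443 for the patient and 0.0277 to 0.353 for the controls on a scale from control mean to patient mean, so a wrong label and poor quality cannot be told apart from a patient tissue that differs little from controls; the labels give no degree of inflammation, and no biological explanation was tested.

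Elsewhere among patients the lowest enteroendocrine score was 8.044 (next 8.898). Single patients also stood apart with the highest CPA3 at 11.78 and IFI27 at 13.19, and with the lowest LMOD1 at 9.451, STMN2 at 6.690 and NCF1 at 9.031. Among the 4 controls single values stood apart on the low side for LILRB3 at 6.870, CD163 at 10.19, CST7 at 8.598, CCL23 at 9.253 and UQCRC1 at 11.96. On the high side they were POU2AF1 at 14.90, PECAM1 at 13.20, BCL2A1 at 12.17, MX2 at 11.53, VCAM1 at 13.20, AURKA at 11.25 and TGFA at 10.36. IL11 at 6.703 was the highest control only because the other 3 controls were at the floor.

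Over all tested genes the median log2 change was -0.05. Among genes past the test those lower in patients outnumbered those higher, 190 to 49, and the arrays of patients had a lower median signal. That balance moved with single arrays: it was 319 to 194 without the patient array near the controls, 197 to 91 without another patient, 96 to 12 without yet another and 66 to 8 without 1 control. With array weights it was 794 to 450. If scaling of the arrays had produced the lower genes, quantile normalization should have cut them to under 95, and a count of at least 126.7 was set beforehand as the bound against that explanation. It left 148, so scaling is argued against as the main source. Different RNA composition of the tissues stays open and was not tested separately. A difference in RNA quality stays open too, since the table held no control probe sets to measure it.

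Lists of resident tissue were mostly lower in patients, which may reflect dilution by infiltrating cells. The pan-epithelial score differed by -1.43 and the endothelial score by 0.29. The difference between them had an exact permutation p of 0.0157 adjusted over 15 pairs of lists, which met the bound set beforehand against even dilution. A rise in the endothelial list itself would give such a difference under even dilution too, so this pair cannot decide. The pan-epithelial change did not differ from that of smooth muscle (exact permutation adjusted p = 0.164), enteric neuron (0.101), enteric glia (0.462) or fibroblast and matrix (0.0749). Enteric glia, with 3 members, differed from enteric neuron (0.0252) and from fibroblast and matrix (0.0490). Even dilution, a loss of epithelial cells, lower transcription within them and a rise in the endothelial list stay open, and were not told apart by any test.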

How the results depend on the processing

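The leave-one-out fits with a looser filter were chosen after the data were seen, the other settings before. The 239 genes changed and the 180 changed at least 2-fold stayed within 1.5 times of these counts under both other scalings, the values as deposited, the other floors, no filter, the mean of probe sets, every probe set on its own, and both other eBayes settings (170 to 313 and 123 to 221 genes). The genes themselves were kept less well than the counts. Of the 239, 121 passed without a filter and 175 with every probe set on its own. Scaling to the 75th percentile kept 180, quantile normalization 183, and the rest of these settings 219 to 237. With the filter at the 75th percentile, 61 and 47 genes passed among 4377 tested. With array weights, 1244 and 559 passed; the 1 patient array near the controls had the lowest weight, 0.421, and all 239 genes were among the 1244. With each array left out in turn the counts ran from 0 to 513 genes, and from 0 to 365 changed at least 2-fold. The 0 came without either of 2 controls. All 230 of the 239 genes still tested kept their sign in each. They were chosen with the left-out control included, and each fit reused all the other arrays. The kept sign was thus nearly fixed in advance and is no evidence that these genes differ between the groups. The count of genes past the test stayed 0 with the filter loosened to 3 arrays (limma, smallest adjusted p = 0.077 and 0.0788). In those fits 1212 and 1084 genes had an unadjusted p under 0.05. The 513 came without the patient array near the controls, picked because of its position, so that count favours a larger difference. Genes higher in patients made up 20.5% of those changed, 10.8% (without 1 control) to 37.8% (without that array) where a fit with 1 array left out called genes, and 36.2% with array weights.

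Camera called 19 to 25 lists over the arrays left out in turn and 20 to 24 over the other processing settings, against 24. With an estimated correlation it called 0, and fry called 5. List scores past adjustment were 0, but 6 with the median over members, 0 with standardized members, and 0 to 9 with arrays left out. Of 199 named genes, the 24 with the larger changes and 19 others passed with the main settings. Of the alternative values of named genes 4468 kept their side of the threshold, 283 were no longer past it and 153 came past it. The 4468 include values of genes that passed in neither setting. The 283 can come only from genes that passed, so they are a larger share of those than the totals show. Of the 283, 216 came with an array left out. For lists the counts were 1132, 89 and 13, and the 1132 include lists called in neither setting. No value that passed changed sign, which the reuse of nearly the same arrays made likely in advance. The cause of these differences was not tested. The fits with a GAPDH ratio were not run, since the table held no control probe sets. TREM1 and AQP8 did not pass in 6 of 12 settings with all arrays, nor AQP9 in 6 and TIMP1 in 7. Quantile normalization ended the camera call of the interferon gamma list (adjusted p = 0.0679) and added MHC class II (0.030). Signal near the floor limits genes such as CHP2, IL11 and MARCO.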

Other observations

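The families below were picked after the results had been seen, partly for their members, so their tests are not independent evidence. Among 7 tested leukocyte immunoglobulin-like receptors 3 rose (LILRA1, LILRB1 and LILRB2), with a median log2 change of 2.33 and an exact permutation p of 0.0168 adjusted over 6 families. Of 5 UDP-glucuronosyltransferases and alcohol dehydrogenases 3 fell (ADH1C, UGT2A3 and UGT2B15), with a median of -2.24 (exact permutation adjusted p = 0.0042). The probe sets of UGT2A3 and UGT2B15 are both of the class that can bind transcripts of related genes, so they are not certain to be separate measurements. Of 6 claudins CLDN3 and CLDN4 fell, with a median of -1.21 (exact permutation adjusted p = 0.0042). The 34 proteasome subunits had a median of 0.20 with 0 members past the limma test (exact permutation adjusted p = 0.0378). By camera with an estimated correlation only the claudins passed (adjusted p = 0.0413 over 6 families). That camera adjusted p was 0.0585 for the leukocyte receptors, 0.0585 for the glucuronosyltransferases and dehydrogenases, and 0.0917 for the proteasome subunits. Of 129 solute carriers 4 fell (SLC1A1, SLC26A2, SLC39A4 and SLC4A4) and the family did not pass (exact permutation adjusted p = 0.388), nor did the 5 aquaporins, of which AQP9 rose and AQP8 fell (exact permutation adjusted p = 0.734).

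Without the patient array near the controls, 15 of 17 neutrophil genes rose over all genes tested and 10 of 13 absorptive colonocyte genes fell, and 9 list scores passed adjustment by exact permutation. At the same time camera no longer called the goblet cell (adjusted p = 0.0801), enteric neuron (0.0651) and immediate early (0.126) lists. Leaving out that array was planned for every array in turn, but singling it out followed from its values.

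Chance was tested with 100 splits of the 13 arrays into 9 and 4, the real one included. Only the real split, 1 of 100, gave as many as 239 genes, the highest other giving 146, and 1 of 100 gave as many as 180 genes changed at least 2-fold, the highest other giving 106. At a share of 1 in 100 splits, with most possible splits not drawn, chance can be excluded at the 0.05 level for both counts over these 13 arrays, although 0 genes passed in limma without either of 2 controls (1165 and 1045 at an unadjusted p under 0.05). For lists 18 of 100 splits gave as many as 24, the highest other giving 31 and the median of the others 16, so chance cannot be excluded for the number of lists called by camera.

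It was set down beforehand that patients with more neutrophil signal may have less absorptive colonocyte signal. Over the 9 patients Pearson's r was -0.4882 (exact permutation p = 0.183) and Spearman's rho -0.467 (exact permutation p = 0.213), with adjusted p of 0.275 and 0.319 over 3 relations, and r was -0.54 without the 2 patients farthest from the median neutrophil score; 9 patients leave this undecided. The neutrophil and pan-epithelial scores had an r of -0.02 and a rho of -0.10 (exact permutation p = 0.952 and 0.810). The neutrophil and B cell scores, for which no direction had been set down, had an r of -0.776 (exact permutation p = 0.0147, adjusted 0.0442) and a rho of -0.833 (exact permutation p = 0.00827, adjusted 0.0248), and r was -0.68 without the 2 farthest patients.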
